A study of Mus musculus with 39 samples.

How the data were processed

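RNA of whole hearts from C57BL/6 mice was measured by tag sequencing of transcript 3' ends. Per the labels' protocols, RNA was taken from frozen hearts and turned into libraries with the Lexogen QuantSeq 3' mRNA-Seq FWD kit, which gives reads near the polyadenylated end of a transcript. The labels give 2 genotypes, wild type and heterozygous for the S55L mutation of Chchd10, at 4 postnatal ages of 30, 75, 125 and 225 d. They name 39 libraries as separate replicates of 8 groups but do not say that each came from its own animal, so p-values measure the spread between these libraries, part of which may be technical. Sex, litter and sequencing batch were not given in the sources used here. At 30 d Xist had 983, 0 and 2 reads in wild-type and 0, 1 and 1 in mutant libraries, so sex was not balanced between these groups. At later ages both genotypes held libraries rich in Xist, in unequal shares at 125 d and 225 d. Libraries rich in Xist held 4 Y-linked reads at 30 d but 113 to 358 at later ages, and the reason was not tested.

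The deposited values are whole-number read counts per Ensembl gene, 1 file per library, with no normalization. The submitters' processing notes name STAR 2.5.0a, HTSeq 0.6.1 and the genome build GRCm38.p6, which per these notes were part of making the counts. Trimming, the handling of molecular identifiers, the strand setting and the annotation release were not given in the sources used here. Without molecular identifiers, reads copied by PCR count more than once, so errors from counting alone would be too small, and no p-value or standard error here rests on them. Reads of overlapping genes on opposite strands, and of near-identical paralogs, may be exchanged. A 3' tag measures the amount of transcript near its end and carries no information on splicing or on a point mutation upstream of it.

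The 6 files of 30 d held 55401 gene identifiers and the 33 files of the later ages 55385. The 55382 identifiers found in all files were used, and the other 22, which held up to 0.937% of a library's counts, were left out. Among those used, 151 carried another version number in the 30 d files than in the later files, so comparisons between 30 d and later ages compare files made with slightly different annotation. Comparisons of genotypes within an age do not. Gene symbols and coordinates were taken from GENCODE M21, which is on the same build and named 55141 of the identifiers. All coordinates are 1-based.

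Libraries held 3.31 to 9.37 M counts (M for mega). Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr on the 8 groups, which left 13735 genes, and libraries were scaled by the trimmed mean of M-values. One quasi-likelihood model with 8 groups and robust estimates of the spread was fitted to all libraries, with 31 residual degrees of freedom. Every adjusted p-value for a gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, at a threshold of 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of the F statistic. Levels are in CPM, counts scaled to a library total of 1 M after the trimmed-mean correction, and are given as mean ± SD over libraries. The 9 contrasts tested were mutant against wild type at each age, 4 differences of that effect between ages (interactions), and wild type at 225 d against 30 d. The smallest chi-square per degree of freedom between libraries of one group was 4.76. It allows for counting error only, and reads copied by PCR raise it, so it does not tell whether libraries came from separate animals.

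Before the data were examined, 45 gene lists of pathways, complexes and cell types were written down, of which 43 had at least 3 tested genes apart from a list of sex-linked genes kept as a check. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the 43 lists. Camera asks whether the genes of a list rank higher or lower than the other genes. It was repeated with the correlation estimated from the data, which lowers power where genes of a list move together. The fry test, which asks whether a list's genes move one way on balance without comparing them with other genes, was a further alternative. Counts of members "adjusted over the list alone" apply Benjamini-Hochberg to the members' p-values only. Chosen at the same time were the groups, the model, the alternatives and the rule for naming genes. That rule names Chchd10 and Chchd2 in every comparison, a panel of 30 genes at all ages (1 of them is not reported here), the 10 largest rises and falls at each age, and up to 4 called members with the smallest p-value of each called list. The largest rises and falls were taken among called genes with an average log2 CPM of at least 2 whose mutant libraries all lay on one side of the wild-type mean, leaving out predicted genes and sex-linked genes. For interactions the 5 largest in each direction were named.

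The scripts were tested on simulated counts with 200 genes changed by known folds. These were drawn with the real library sizes and with 1 mean and 1 spread per gene for all libraries. Real libraries of a group differed by a chi-square per degree of freedom of 19.2 to 75.6 at 30 d and 5.79 to 18.8 at 75 d. At 125 d it reached 290 among mutants. The shares for 30 d and 125 d may therefore not hold for the real libraries. For the 30 d comparison, run on 13490 genes, 66.7% of genes changed 4-fold and 6.15% of those changed 2-fold were called. At 75 d these shares were 84.1% and 37.3% (13473 genes), at 125 d 87.7% and 39.4% (13500 genes), and at 225 d 92.3% and 50.7% (13463 genes). For the interaction of 225 d against 30 d they were 50.8% and 4.62% (13431 genes), and for wild type at 225 d against 30 d 80.3% and 25.4% (13523 genes). Between 0 and 9 unchanged genes were called.

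Alternatives written down beforehand were median-of-ratios size factors, no filter beyond 1 read in any library, DESeq2 1.42.0, a fit of only the ages compared, the replicate number as a block, the level of Xist as a covariate in place of the sex missing from the labels, limma's voom with quality weights, and leaving out each library in turn. Chosen after seeing the data were 3 more, namely leaving out 4 libraries with RNA of another organ (Scgb1a1, a secretory protein of airway cells, or Dntt, a polymerase of thymocytes, above 10 CPM), the level of atrial genes as a covariate, and total counts as size factors. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No fold is given for genes with 3 or fewer reads in all libraries of a group together, or close to it, which are given by CPM.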

Results

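Hearts of mice that carry 1 copy of the S55L mutation in Chchd10, a small protein of the mitochondrial intermembrane space, were compared with wild-type hearts by 3' tag sequencing. The study title places the mutation in a mouse model of mitochondrial cardiomyopathy. Wild-type (WT) hearts gave 3, 5, 6 and 7 libraries at 30, 75, 125 and 225 d of age, and mutant hearts gave 3, 5, 5 and 5. Libraries held 3.31 to 9.37 M counts, with the shallowest among the 30 d mutants (3.31 to 5.16 M), and 15869 to 19337 genes had at least 1 read. Transcripts of the mitochondrial genome took 39.8 ± 3.92% of the counts in WT hearts at 30 d, 41.9 ± 1.82% at 75 d, 42.4 ± 3.26% at 125 d and 43.3 ± 3.38% at 225 d (SD). In mutant hearts they took 32.4 ± 6.34%, 32.3 ± 1.22%, 25.8 ± 6.93% and 32.0 ± 3.13% at the same ages. The 125 d mutant value includes 14.8% in replicate 4, which held RNA of another organ, where the other libraries held 23.3 to 31.2%. A single gene, mt-Nd4, took 8.96 to 27.5% of the counts of a library. The deposited read counts were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment over 13735 genes, and "called" means an adjusted p under 0.05. Errors of log2 fold changes are standard errors, and levels are CPM as mean ± SD.

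In 4 libraries RNA of other organs was found. Dntt, a polymerase of developing lymphocytes, stood at 1257 CPM in 125 d mutant replicate 4 and at 22.8 CPM in 75 d WT replicate 5. Scgb1a1, a secretory protein of airway cells, stood at 640 CPM in 125 d mutant replicate 1 and at 1085 CPM in 225 d WT replicate 6. The total number of called genes in each comparison is therefore also given without these 4 libraries.

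Chchd10 itself (ENSMUSG00000049422; GRCm38.p6, chromosome 10, 75933130 to 75937747) was not called at any age. Its log2 fold change in mutant hearts was 0.30 ± 0.45 at 30 d, 0.45 ± 0.35 at 75 d, 0.33 ± 0.33 at 125 d and 0.75 ± 0.32 at 225 d, where the adjusted p was 0.0941. Levels were 2211 ± 1007 CPM in mutant and 1800 ± 906 CPM in WT hearts at 30 d (n = 3 and 3), and 3365 ± 586 against 2002 ± 252 CPM at 225 d (n = 5 and 7). With the 4 libraries left out, Chchd10 was called at 125 d (0.78) and 225 d (0.75). The mutation changes 1 base, and a tag at the 3' end does not read it, so these levels do not check the genotype labels. Chchd2, the closest relative of Chchd10, was listed at 0 in every library. This does not show that it was not expressed, because the counting settings were not given in the sources used here.

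**Figure D1:**
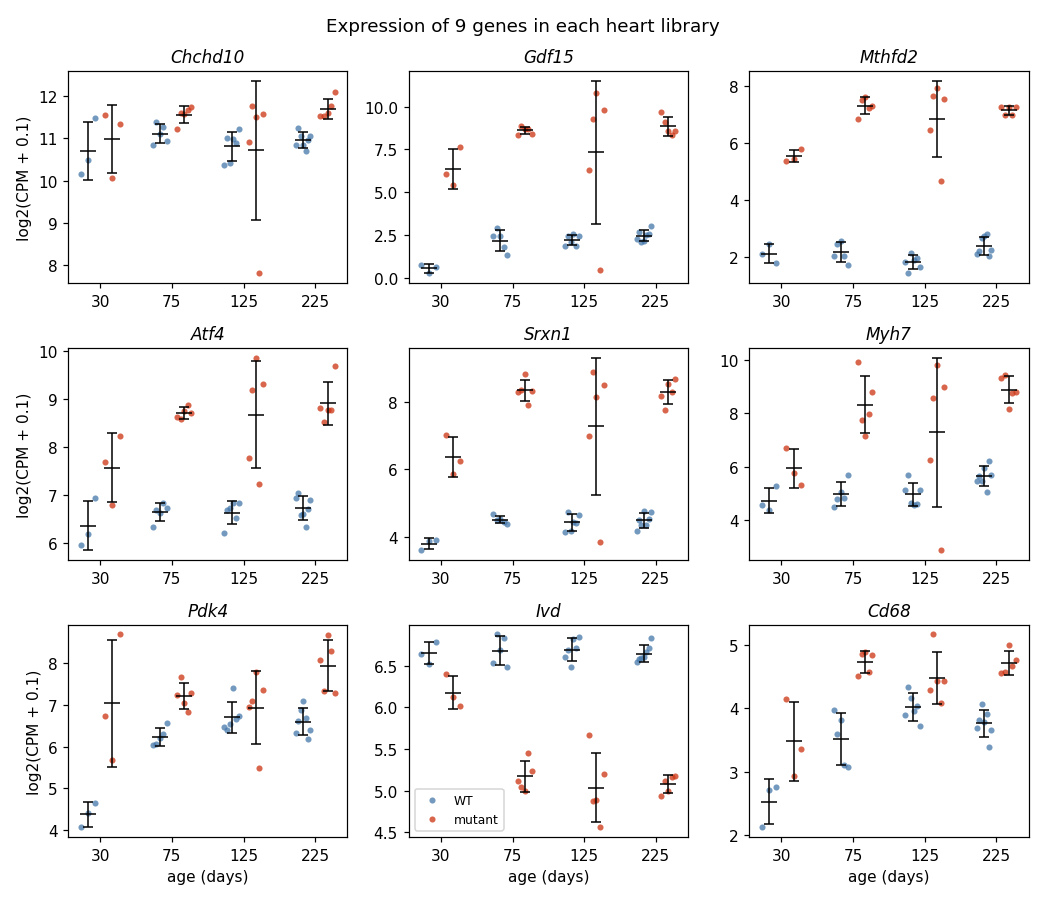
Each panel plots 1 gene, with log2(CPM + 0.1) on the y axis and age in days on the x axis. Points are single libraries (WT blue, mutant red), and bars give the mean ± SD of the log values. Mthfd2 lies higher in mutant libraries at every age, with mean levels of 47.0 against 4.36 CPM at 30 d and 144 against 5.31 CPM at 225 d, while Ivd lies lower from 75 d on, with 36.2 against 103 CPM at 75 d.

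At 30 d the question was whether any transcripts already differed in young hearts. Mthfd2, the mitochondrial folate enzyme of one-carbon metabolism (ENSMUSG00000005667; chromosome 6, 83305691 to 83325908), rose by 3.41 ± 0.44 on the log2 scale, from 4.36 ± 1.06 to 47.0 ± 7.20 CPM (adjusted p = 2.87e-05). Txnrd1, the cytosolic thioredoxin reductase (ENSMUSG00000020250; chromosome 10, 82833951 to 82897712), rose by 2.13 ± 0.32 (adjusted p = 0.000499). Gdf15, a secreted stress hormone (ENSMUSG00000038508; chromosome 8, 70629393 to 70632456), rose by 6.17 ± 1.16. Pdk4, the kinase that inhibits pyruvate dehydrogenase (ENSMUSG00000019577; chromosome 6, 5483351 to 5496309), rose by 3.19 ± 0.50. Srxn1, which repairs oxidised peroxiredoxins (ENSMUSG00000032802; chromosome 2, 152105516 to 152111376), Psat1 of serine synthesis (ENSMUSG00000024640; chromosome 19, 15904678 to 15947337) and the cadherin Cdh4 (ENSMUSG00000000305; chromosome 2, 179442431 to 179899373) also rose, by 2.67 ± 0.53, 2.54 ± 0.45 and 2.13 ± 0.43. In each of these 7 genes all 3 mutant libraries lay above the WT mean, which the naming rule requires of the largest rises, and no gene fell.

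Among the gene groups at 30 d, targets of the antioxidant regulator NRF2 were higher than other genes, with a mean log2 fold change of 1.26. Of the 15 measured, 2 rose and 13 were not called, and 8 rose when adjusted over the list alone (list adjusted p = 0.0109 with an estimated correlation). Genes of serine and folate one-carbon metabolism were higher, with 2 of 20 rising, 18 not called and 2 rising adjusted over the list alone (adjusted p = 0.0202 with an estimated correlation), a call that ended without mutant replicate 1 (mean 0.38 in place of 0.47). Macrophage markers were higher with a mean of 0.76, with 0 of 14 called and 2 rising adjusted over the list alone (adjusted p = 0.0320 with an estimated correlation). Other lists of cells and tissue were higher with the preset correlation only and with 0 genes called. They were red blood cell genes (mean 1.17), cell cycle genes (1.44) and matrix and fibrosis genes (0.41), with an adjusted p of 0.754, 0.432 and 0.754 with an estimated correlation. The red blood cell list (0.21) was not called without mutant replicate 3, and the matrix list (0.30) not without mutant replicate 2. The integrated stress response, the programme driven by ATF4 that raises amino acid supply, had a mean of 0.99 with 1 of 24 genes called and 5 adjusted over the list alone. Its call rested on the preset correlation (adjusted p = 0.320 with an estimated correlation). Aminoacyl-tRNA synthetases had a mean of 0.39 with 0 of 20 called, also adjusted over the list alone (adjusted p = 0.320 with an estimated correlation). Interferon response genes had a mean of 0.51 with 0 of 17 called and 3 adjusted over the list alone (adjusted p = 0.127 with an estimated correlation). Among stress genes that were not called, the log2 fold change was 3.42 for Trib3, 3.08 for Asns and 1.25 for Atf4. Only 7 messenger RNAs of the mitochondrial genome passed the filter on low counts and were tested. They had a mean of -0.48, and 1 was lower adjusted over the list alone, but the list was not called (adjusted p = 0.0542). Complex I (mean -0.16), complex IV (-0.27), branched-chain amino acid breakdown (-0.26) and clock genes (-0.42) were lower with 0 genes called, and all 4 calls were lost with an estimated correlation (adjusted p = 0.992, 0.855, 0.279 and 0.226). They were also lost without WT replicate 3 (0.0687, -0.03, -0.12 and -0.34), and the complex I mean turned to 0.04 with total counts as size factors. Of 15 called lists, 11 higher and 4 lower, 3 held with an estimated correlation.

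In all, 7 genes rose and 0 fell at 30 d, where 764 genes had an unadjusted p under 0.05, DESeq2 called 25 and limma's voom with quality weights 21. A fit of only this age called 9, with 301 at an unadjusted p under 0.05. Chance alone gives an unadjusted p under 0.05 to a share of about 0.05 of unchanged genes. Unadjusted counts here and below are to be read against that share. With the 4 libraries left out, none of which is of this age, 74 genes were called (61 higher and 13 lower). With total counts as size factors 97.8% of 45 called genes were higher, and the median gene lay 0.19 higher in mutant hearts on the log2 scale. Mthfd2 (3.26 to 3.62) and Txnrd1 (2.06 to 2.25) were called whichever library was left out and under every alternative. With only this age in the fit Pdk4 (3.22), Psat1 (2.56) and Cdh4 (2.14) were not called. The calls of Gdf15 (6.19) and Srxn1 (2.68) ended with no filter on low counts, those of Srxn1 (2.57) and Cdh4 (2.01) with the Xist covariate, and those of Psat1 (2.07) and Cdh4 (2.59) with voom. Without WT replicate 1, 2 or 3 neither Gdf15 (6.30, 6.01 and 6.21) nor Srxn1 (2.60, 2.71 and 2.72) was called, and Psat1 was not without WT replicate 1 (2.29) or 3 (2.64). Cdh4 was not called whichever library was left out (1.88 at the lowest), and Srxn1 not without mutant replicate 1 (2.27) or 3 (2.78). Without mutant replicate 3 Pdk4 stood at 1.93 and Gdf15 at 5.28, and without mutant replicate 1 Psat1 stood at 1.96, none of them called. The number of called genes was 3 without WT replicate 1 or WT replicate 3, and 4 without WT replicate 2, mutant replicate 1 or mutant replicate 3.

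At 75 d, the question was which pathways differed in adult hearts. Stress and amino acid genes stood at many times their WT levels. Gdf15 rose by 6.37 ± 0.85 on the log2 scale, from 4.81 ± 1.91 to 394 ± 61.7 CPM (adjusted p = 2.59e-06). Mthfd2 rose by 5.18 ± 0.35, from 4.50 ± 1.11 to 162 ± 31.3 CPM (adjusted p = 5.71e-13). Asparagine synthetase Asns (ENSMUSG00000029752; chromosome 6, 7675169 to 7693254) rose by 5.17 ± 0.56, and Phgdh (ENSMUSG00000053398; chromosome 3, 98313170 to 98339990), which opens the serine pathway, by 5.18 ± 0.55 from 0.254 ± 0.258 to 9.93 ± 3.02 CPM. Atf4 (ENSMUSG00000042406; chromosome 15, 80255184 to 80257541), the transcription factor of the integrated stress response, rose by 2.06 ± 0.31, from 101 ± 12.5 to 421 ± 35.5 CPM (adjusted p = 1.15e-05). Ivd (ENSMUSG00000027332; chromosome 2, 118861954 to 118882909), isovaleryl-CoA dehydrogenase of leucine breakdown, fell by 1.51 ± 0.15, from 103 ± 12.3 to 36.2 ± 4.83 CPM (adjusted p = 9.12e-09). For each gene named here as rising or falling at 75 d, all 5 mutant libraries lay on that side of the WT mean. The naming rule requires this of the largest rises and falls.

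Among the groups that were higher at 75 d were those of amino acid, redox and stress metabolism and macrophage markers. In the integrated stress response 17 of 24 genes rose, 1 fell and 6 were not called (18 and 1 adjusted over the list alone), with Trib3 at 4.12 ± 0.52, Atf5 at 2.49 ± 0.48 and Ddit3 at 1.34 ± 0.37 (list adjusted p = 0.0355 with an estimated correlation). Of 20 aminoacyl-tRNA synthetases, which load tRNAs with amino acids, 15 rose and 5 were not called (16 adjusted over the list alone), for example Gars (2.23 ± 0.29) and Aars (1.33 ± 0.20), and the list adjusted p was 0.0196 with an estimated correlation. In serine and one-carbon metabolism 7 of 20 rose and 13 were not called (8 rose and 1 fell adjusted over the list alone), with Psat1 at 4.24 ± 0.33 and Shmt2 at 1.39 ± 0.25 (adjusted p = 8.59e-05 with an estimated correlation). Of 15 NRF2 targets 13 rose and 2 were not called, among them Srxn1 (3.87 ± 0.43), Nqo1 (2.71 ± 0.36), Gclm (2.57 ± 0.38) and Txnrd1 (2.13 ± 0.25; list adjusted p = 0.00857 with an estimated correlation). In proline synthesis Pycr1 (3.50 ± 0.46) and Aldh18a1 (2.88 ± 0.39) rose and Prodh, which degrades proline, was lower by 1.21 ± 0.28, with 2 of 5 genes not called (adjusted p = 0.0893 with an estimated correlation). Macrophage markers rose in 10 of 14 genes with 4 not called (12 adjusted over the list alone), with Lgals3 at 2.29 ± 0.41 and Cd68 at 1.20 ± 0.20 (26.7 ± 3.19 against 11.7 ± 3.24 CPM; list adjusted p = 0.00986 with an estimated correlation).

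The group that fell most clearly at 75 d was branched-chain amino acid breakdown, with 12 of 20 genes lower and 8 not called (14 lower adjusted over the list alone). Ppm1k, the phosphatase that activates this pathway (ENSMUSG00000037826; chromosome 6, 57506502 to 57535468), fell by 1.91 ± 0.21 and Dbt by 1.11 ± 0.16 (list adjusted p = 0.0196 with an estimated correlation). Nuclear subunits of complex I had a mean log2 fold change of -0.43 with 4 of 35 lower and 31 not called (8 lower adjusted over the list alone), and the list call was lost with an estimated correlation (adjusted p = 0.534). The 7 tested messenger RNAs of the mitochondrial genome had a mean of -0.55, with 2 lower and 5 not called. Adjusted over the list alone 6 were lower (list adjusted p = 0.563 with an estimated correlation). That list was not called without WT replicate 2 or 3 or mutant replicate 1 or 4, nor without a filter on low counts (mean -0.32). In fatty acid uptake and oxidation 5 of 26 genes fell, 2 rose and 19 were not called (6 and 3 adjusted over the list alone), with Acaa2 at -0.96 ± 0.24 and Cpt1a at 0.62 ± 0.16. The mean of this fatty acid list of -0.28 turned to 0.02 with total counts as size factors (adjusted p = 0.563 with an estimated correlation). Genes of adult contraction and calcium handling were lower in 6 of 21 with 15 not called, the same 6 adjusted over the list alone, with the calcium pump Atp2a2 at -1.05 ± 0.23 and its inhibitor Pln (ENSMUSG00000038583; chromosome 10, 53337667 to 53345987) at -0.84 ± 0.20 (list adjusted p = 0.6 with an estimated correlation).

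Genes of the fetal and stressed heart rose in 5 of 13 with 8 not called (6 adjusted over the list alone) at 75 d, but the list call was lost with an estimated correlation (adjusted p = 0.104). Myh7 (ENSMUSG00000053093; chromosome 14, 54970684 to 54994626), the myosin heavy chain of the fetal ventricle, rose by 3.62 ± 0.64, Nmrk2 (ENSMUSG00000004939; chromosome 10, 81198170 to 81202051), a kinase of NAD synthesis, by 3.47 ± 0.51, and Ankrd1, a stretch-responsive sarcomere protein, by 2.41 ± 0.46. The natriuretic peptide gene Nppb (1.70, adjusted p = 0.0676) and Myh6 (-0.72, adjusted p = 0.151) were not called. Matrix and fibrosis genes rose in 7 of 23 with 16 not called (13 adjusted over the list alone), with Cilp at 2.62 ± 0.48 and Tgfb2 at 2.59 ± 0.45. Col1a1 was not called (0.92, adjusted p = 0.0540), and the call of the matrix list was lost with an estimated correlation (adjusted p = 0.366). Uchl1, a deubiquitinase best known from neurons (ENSMUSG00000029223; chromosome 5, 66676091 to 66687234), rose by 4.30 ± 0.56 from 13.6 ± 3.06 to 269 ± 63.5 CPM. The glutathione transferase Gsta2 stood at 29.1 ± 12.4 against 0.221 ± 0.156 CPM, with its near-identical copy Gsta1 at 18.7 ± 4.29 against 0.0388 ± 0.0868 CPM, so that reads of the pair cannot be assigned with certainty. Among the largest falls were Lingo3 (-3.28 ± 0.43), Efnb3, an ephrin ligand (ENSMUSG00000003934; chromosome 11, 69554092 to 69560205; -2.74 ± 0.31), and Pfkfb1 (-2.74 ± 0.45).

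At 75 d, 1706 genes (12.4% of those tested) were called, 998 higher and 708 lower, and 928 of them differed more than 2-fold. The count was 2439 (1321 higher and 1118 lower) without the 4 libraries, 3832 (53.5% higher) with only this age in the fit and 4343 (52.2% higher) with voom and quality weights. Higher genes made up 58.5% of the calls, and 88.2% of 2655 calls with total counts as size factors, which moved the median gene by 0.29 on the log2 scale. Ucp1 (-7.56), a brown fat gene, rested on WT replicate 5, without which it stood at 3.41 and was not called, and the smooth muscle gene Myh11 (-1.78) stood at -1.22 without that library and was not called. Of 43 lists, 10 were higher and 14 lower, and 6 of these 24 calls held with an estimated correlation.

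**Figure D2:**
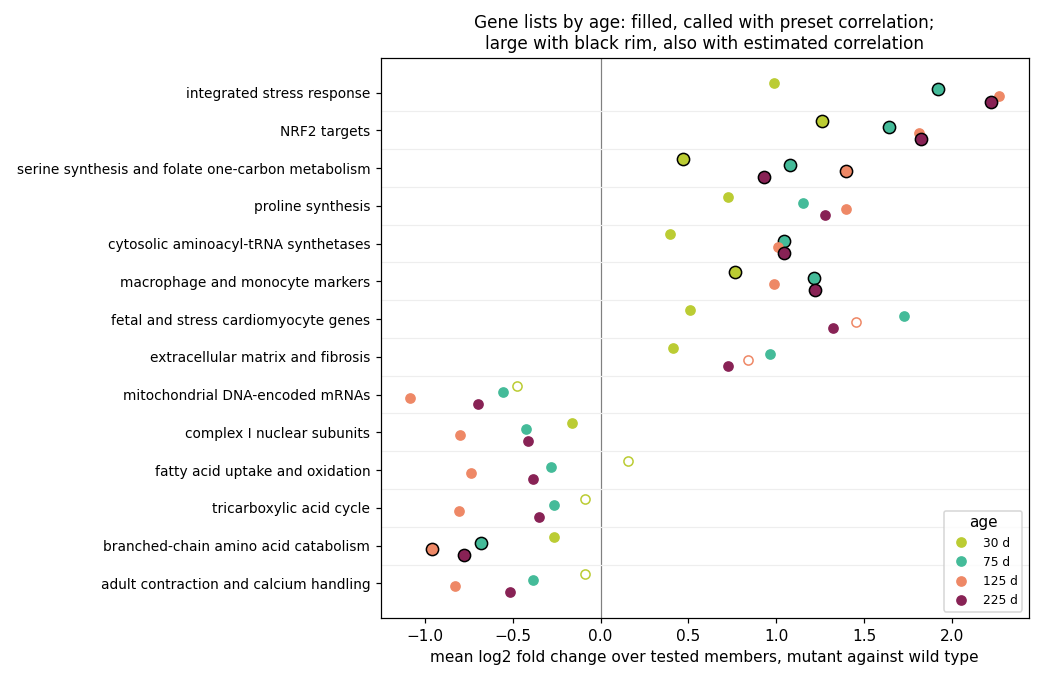
Mean log2 fold change (mutant minus WT, x axis) of the measured genes of each of 14 lists (y axis), with ages by colour. Open points were not called, filled points were called with the preset correlation, and large points with a black rim were also called with an estimated correlation. Serine and one-carbon metabolism has means of 0.47 at 30 d and 1.08 at 75 d, and branched-chain amino acid breakdown has means of -0.26 and -0.68.

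At 125 d replicate 4 of the mutant libraries held high levels of thymus RNA and replicate 1 airway RNA. Pairs of mutant libraries differed by a chi-square per degree of freedom of 9.59 to 290, against 5.79 to 16.5 at 75 d, a measure that allows for counting error only. Replicate 3, which held neither above 10 CPM, also lay far from replicates 2 and 5 (46.8 and 58.4). The stress and amino acid genes were again far above WT. Gdf15 rose by 7.16 ± 0.80, from 4.69 ± 0.957 to 673 ± 711 CPM, with 4 of 5 mutant libraries above the WT mean. Mthfd2 rose by 5.42 ± 0.33 with 5 of 5 (adjusted p = 1.68e-14). Slc7a11 (ENSMUSG00000027737; chromosome 3, 49892526 to 50443614), the cystine transporter, rose by 5.55 ± 0.60 and Asns by 5.29 ± 0.53, each in 5 of 5. Myot (ENSMUSG00000024471; chromosome 18, 44334074 to 44355724), a Z-disc protein of muscle, fell by 4.89 ± 0.43 to 0.293 ± 0.184 CPM (adjusted p = 2.32e-10). Among the other large falls were Efnb3 with -3.60 ± 0.32, Lingo3 with -3.27 ± 0.42 and the protease Adamts7 with -2.92 ± 0.37, all in 5 of 5. The naming rule requires 5 of 5 for the largest rises and falls.

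Transcripts of mitochondrial energy metabolism were lower at 125 d in more genes than at 75 d, a difference between ages that is tested with the interactions. Of 35 complex I genes 27 fell and 8 were not called (29 adjusted over the list alone), with Ndufv2 (ENSMUSG00000024099; chromosome 17, 66078638 to 66101559) at -1.06 ± 0.18, and the list adjusted p was 0.126 with an estimated correlation. The 4 complex II genes fell (mean -1.18; adjusted p = 0.113 with an estimated correlation). Sdha (-0.62) was not called with total counts as size factors (-0.13) or without the 4 libraries (-0.34). Sdhd (-2.08) was not called with voom (-1.62), and neither Sdha nor Sdhb (-0.87) was with only this age in the fit (-0.62 and -0.86). Also lower were 6 of 9 complex III genes (adjusted p = 0.176), 9 of 16 ATP synthase genes (adjusted p = 0.138) and 10 of 13 complex IV genes with 1 higher (adjusted p = 0.247), each with an estimated correlation and the other members not called. With total counts as size factors the means were -0.31 in place of -0.80 for complex I and -0.69 in place of -1.18 for complex II. They were -0.24 in place of -0.72 for complex III, -0.22 in place of -0.71 for complex IV and -0.25 in place of -0.74 for ATP synthase, and Ndufv2 stood at -0.57. Cox7a1, the muscle form of a complex IV subunit, fell by 1.58 ± 0.23. Cox6a1, the form of a different complex IV subunit that is found in other tissues, rose by 1.02 ± 0.17. Of the 7 tested messenger RNAs of the mitochondrial genome 6 fell and 1 was not called (mean -1.08; adjusted p = 0.219 with an estimated correlation). Among them mt-Nd1 (ENSMUSG00000064341; mitochondrial genome, 2751 to 3707) stood at -1.33 ± 0.22 and mt-Cytb (ENSMUSG00000064370; 14145 to 15288) at -1.62 ± 0.30. In fatty acid uptake and oxidation 20 of 26 fell, 1 rose and 5 were not called (20 and 2 adjusted over the list alone), with Acsl1 at -1.32 ± 0.19 (adjusted p = 0.126 with an estimated correlation). In the tricarboxylic acid cycle 14 of 20 fell and 6 were not called (15 adjusted over the list alone), with Sucla2 at -1.05 ± 0.17 (adjusted p = 0.138 with an estimated correlation). Branched-chain amino acid breakdown fell in 17 of 20 genes with 3 not called and ketone body metabolism in 5 of 6 with 1 not called, and both calls held with an estimated correlation (adjusted p = 0.0102 and 0.0204).

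Most of these falls were smaller without the 4 libraries. The mean of the complex I list was -0.56 in place of -0.80, with 20 genes lower, and that of the tricarboxylic acid cycle -0.59 in place of -0.80 with 12 lower. The mean of fatty acid oxidation was -0.48 in place of -0.74 with 15 lower, and that of the mitochondrial messenger RNAs -0.83 in place of -1.08 with 6 lower. Branched-chain amino acid breakdown kept a mean of -0.98 in place of -0.96, with 16 lower. Mitochondrial ribosomal proteins had 20 of 74 lower and 54 not called with a mean of -0.32, which became -0.15 and was not called without the 4 libraries, and 0.21 with total counts as size factors (adjusted p = 0.340 with an estimated correlation). Contraction and calcium genes fell in 13 of 21 with 8 not called, with the calcium pump Atp2a2 at -1.24 ± 0.23 and the calcium release channel Ryr2 at -1.26 ± 0.24 (adjusted p = 0.187 with an estimated correlation), and their mean of -0.83 was -0.46 without the 4 libraries. Endothelial markers fell in 8 of 12 with 4 not called (mean -0.46, -0.21 without mutant replicate 4, and 0.01 with total counts as size factors; adjusted p = 0.247 with an estimated correlation).

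Among the groups that were higher at 125 d were those of stress and amino acid metabolism and macrophage markers. In the integrated stress response 17 of 24 genes rose, 1 fell and 6 were not called, also adjusted over the list alone (adjusted p = 0.126 with an estimated correlation), and without the 4 libraries 18 rose and the estimated-correlation p was 1.55e-05. Aminoacyl-tRNA synthetases rose in 17 of 20 with 3 not called (17 and 1 lower adjusted over the list alone; adjusted p = 0.113 with an estimated correlation) and NRF2 targets in 13 of 15 with 2 not called (14 adjusted over the list alone; adjusted p = 0.0633 with an estimated correlation). Serine and one-carbon metabolism rose in 9 of 20, with 1 lower and 10 not called (adjusted p = 0.000999 with an estimated correlation). Proline synthesis had 4 of 5 higher and 1 lower (adjusted p = 0.113 with an estimated correlation). Macrophage markers rose in 8 of 14 with 6 not called (9 adjusted over the list alone), with Lgals3 at 2.82 ± 0.38 (ENSMUSG00000050335; chromosome 14, 47367751 to 47386160; adjusted p = 0.247 with an estimated correlation). Fetal and stressed heart genes rose in 7 of 13, with 1 lower and 5 not called (8 and 1 adjusted over the list alone), and the list was not called (adjusted p = 0.0682). It was without the 4 libraries, with 7 of 12 higher and a mean of 1.89 (adjusted p = 0.00436 with an estimated correlation). Myh7 rose by 3.50 ± 0.59 with 4 of 5 mutant libraries above the WT mean, and Nppb by 2.34 ± 0.58, or 1.42 without mutant replicate 3.

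Several calls at 125 d rested on 1 library. All 19 cell cycle genes were called higher (mean 3.32; adjusted p = 0.548 with an estimated correlation), but without mutant replicate 4 the mean was -0.10 and the list was not called, with Top2a going from 4.19 to 0.23 and the leukocyte gene Ptprc from 3.35 to 0.39. Without the same library the calls of sterol synthesis (10 of 16 higher, mean 0.38 without it), of the cristae list (6 of 12 lower, 1 higher, mean -0.08 without it) and of smooth muscle markers (-0.00264 without it) also ended. Sterol synthesis was not called without mutant replicate 1 either (0.72). None of these calls held with an estimated correlation. The 6 red blood cell genes fell (mean -1.94; adjusted p = 0.280 with an estimated correlation), and WT replicate 4 held much of that difference, with a list mean of -0.87 and Hbb-bs at -1.04 in place of -1.95 without it. Cytosolic ribosomal proteins were higher in 16 of 79, with 2 lower and 61 not called (13 and 1 adjusted over the list alone; mean 0.21, adjusted p = 0.637 with an estimated correlation). This list was not called without mutant replicate 4 (0.12) or WT replicate 6 (0.18). Acta1 stood at -1.46 and at -0.50, not called, without WT replicate 2.

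In all, 4581 genes (33.4%) were called at 125 d, 2898 higher and 1683 lower, 2253 of them with more than a 2-fold difference. Without the 4 libraries 3835 were called, 2182 higher and 1653 lower (56.9% higher in place of 63.3%), and the median gene moved from 0.17 to 0.01 on the log2 scale. With total counts as size factors 92.6% of 8313 called genes were higher and the median gene lay 0.74 higher. With voom and quality weights 53.9% were higher, with only this age in the fit 53.3% of 1410, and with the replicate number as a block 48.8% of 2839. Of 27 called lists, 9 higher and 18 lower, 3 held with an estimated correlation.

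**Figure D3:**
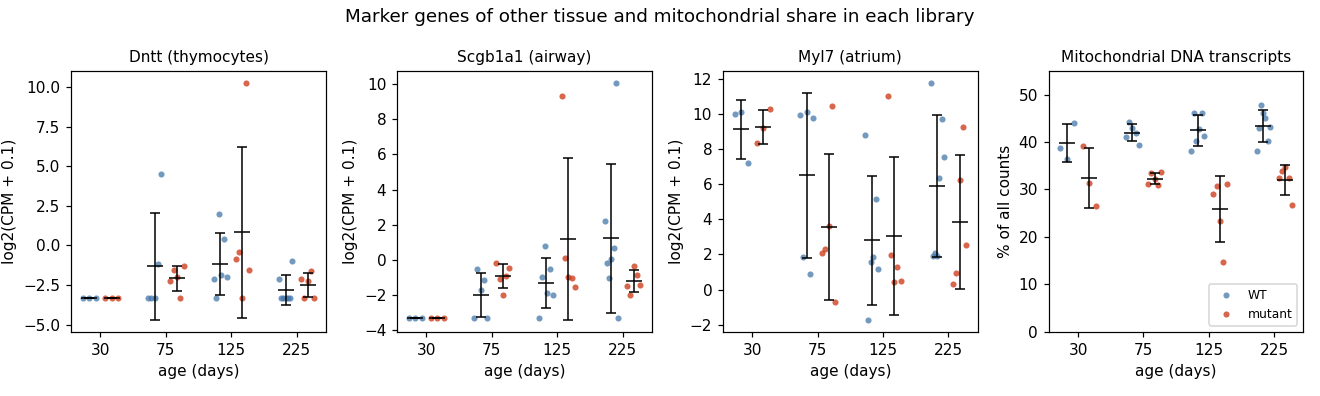
Levels in single libraries, by age in days on the x axis, of Dntt, Scgb1a1 and the atrial gene Myl7 as log2(CPM + 0.1), and the share of counts from the mitochondrial genome in percent (y axes). Points are libraries (WT blue, mutant red), and bars give the mean ± SD. Mutant replicate 4 of 125 d reaches 1257 CPM of Dntt, and WT replicate 6 of 225 d reaches 1085 CPM of Scgb1a1.

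At 225 d the question was which differences were present in the oldest hearts. Gdf15 rose by 6.45 ± 0.73, from 5.62 ± 1.30 to 494 ± 209 CPM (adjusted p = 7.05e-08), Asns by 5.08 ± 0.48, Trib3 (ENSMUSG00000032715; chromosome 2, 152337422 to 152344032) by 4.85 ± 0.46, Phgdh by 4.83 ± 0.47 and Mthfd2 by 4.77 ± 0.30 (adjusted p = 3.84e-14). The microtubule protein Map1a (ENSMUSG00000027254; chromosome 2, 121289600 to 121310832) rose by 5.12 ± 0.53, from 7.22 ± 2.33 to 251 ± 54.9 CPM. Myh7 rose by 3.26 ± 0.55 from 51.7 ± 13.5 to 496 ± 166 CPM, Nmrk2 by 3.22 ± 0.44, and Pdk4 by 1.41 ± 0.32 from 99.2 ± 22.7 to 264 ± 109 CPM. Myot fell by 4.44 ± 0.40 and Efnb3 by 3.65 ± 0.32. For every gene of this paragraph all 5 mutant libraries lay on the same side of the WT mean, which the naming rule requires of the largest rises and falls.

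The integrated stress response rose in 17 of 24 genes at 225 d, with 1 lower and 6 not called (18 and 1 adjusted over the list alone; adjusted p = 0.0300 with an estimated correlation), with Atf4 at 2.22 ± 0.28 and Atf5 at 3.18 ± 0.44. Aminoacyl-tRNA synthetases rose in 15 of 20 with 5 not called (17 adjusted over the list alone; adjusted p = 0.0273 with an estimated correlation). NRF2 targets rose in 12 of 15 with 3 not called (13 adjusted over the list alone; adjusted p = 0.0181 with an estimated correlation), and serine and one-carbon genes in 7 of 20, with 2 lower and 11 not called (8 and 2 adjusted over the list alone; adjusted p = 0.00428 with an estimated correlation). Proline synthesis had 3 of 5 higher, 1 lower and 1 not called (adjusted p = 0.0505 with an estimated correlation). In glutathione and transsulfuration metabolism 10 of 24 rose and 3 fell (11 and 3 adjusted over the list alone), with the transferase Gstm1 at 2.37 ± 0.37 and Gstk1 at -1.84 ± 0.21, and the list call was lost with an estimated correlation (adjusted p = 0.567) or without mutant replicate 5 (mean 0.40 in place of 0.51). Macrophage markers rose in 12 of 14 with 2 not called (adjusted p = 0.0190 with an estimated correlation), with Lgals3 at 2.64 ± 0.36, the complement gene C1qc at 1.35 ± 0.24 and Aif1 at 1.09 ± 0.19. Branched-chain amino acid breakdown fell in 13 of 20 with 7 not called (16 adjusted over the list alone; adjusted p = 0.0190 with an estimated correlation), with Ivd at -1.57 ± 0.14, Ppm1k at -1.90 ± 0.20 and Mccc1 at -0.94 ± 0.14.

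Fewer energy metabolism genes were called at 225 d than at 125 d, although no interaction between these ages was called for a gene. Of the 7 tested messenger RNAs of the mitochondrial genome 6 fell and 1 was not called (mean -0.70; adjusted p = 0.567 with an estimated correlation). Among them mt-Nd2 stood at -0.96 ± 0.24. The list was not called without a filter on low counts (mean -0.52). Complex I genes had a mean of -0.42 with 5 of 35 lower and 30 not called (10 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), of which Ndufa10 fell by 0.80 ± 0.21. Fatty acid uptake and oxidation had 10 of 26 lower, 3 higher and 13 not called (11 and 3 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), with Etfdh at -1.24 ± 0.23. The tricarboxylic acid cycle had 1 of 20 lower and 19 not called, 0 adjusted over the list alone, and its mean of -0.35 turned to 0.02 with total counts as size factors (adjusted p = 0.623 with an estimated correlation). Contraction and calcium genes fell in 7 of 21 with 14 not called, with Ryr2 at -1.18 ± 0.23 and the potassium channel Kcnd2 at -1.26 ± 0.24 (adjusted p = 0.567 with an estimated correlation). Fetal and stressed heart genes rose in 5 of 13 with 8 not called (adjusted p = 0.316 with an estimated correlation), and matrix and fibrosis genes in 7 of 23 with 16 not called (8 adjusted over the list alone; adjusted p = 0.567 with an estimated correlation), with Comp at 3.16 ± 0.66 and Ltbp2 at 2.14 ± 0.56.

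At 225 d, 2559 genes (18.6%) were called, 1434 higher and 1125 lower, 1210 with more than a 2-fold difference. The count was 3560 (1945 higher and 1615 lower) without the 4 libraries, 3979 (53.3% higher) with only this age in the fit and 4800 (53.0% higher) with voom and quality weights. Higher genes made up 56.0% of the calls, and 89.1% of 4297 with total counts as size factors, which moved the median gene by 0.35 on the log2 scale. WT replicate 6 held airway RNA. Without it Bpifa1 went from -10.16 to -2.14 and Scgb1a1 from -8.65 to -1.85, and neither was called. The adipocyte list, with 1 of 8 genes lower and 7 not called (8 lower adjusted over the list alone), went from -4.45 to -2.27 without it (adjusted p = 0.635 with an estimated correlation). Hmox1 (1.79) was not called without mutant replicate 5 (1.00), nor Bmp10 (5.75) without mutant replicate 4 (4.37). Of 22 called lists, 10 higher and 12 lower, 6 held with an estimated correlation.

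The ages were compared in 2 ways. Across all 13735 genes, which are not independent replicates, the log2 fold changes of 75 d and 225 d correlated with Pearson r = 0.78 and Spearman rho = 0.76. Those of 75 d and 125 d correlated with 0.42 and 0.50, those of 125 d and 225 d with 0.45 and 0.58, and those of 30 d with the later ages with Pearson r of 0.48, 0.35 and 0.47. The 125 d fold changes include mutant replicate 4, which held thymus RNA, and mutant replicate 1, which held airway RNA. The correlations were not repeated without the 4 libraries, so whether these libraries lower the values with 125 d was not tested. Each age had its own WT libraries. At both 75 d and 225 d 814 genes were called higher, where 104 would be shared by independent lists. For lower genes the counts were 570 and 58.0. Only 1 gene was called in opposite directions, Bmp10, which was lower at 75 d and higher at 225 d. Its call at 75 d ended without WT replicate 1 or 5 or any single mutant library. At 225 d its call ended without mutant replicate 4. Of the 1706 genes called at 75 d, 1695 had the same sign at 225 d and 1661 at 125 d.

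The interaction tests asked whether the effect of the mutation itself differed between ages. For 75 d minus 30 d, 0 genes were called by edgeR (816 at an unadjusted p under 0.05), 3 by DESeq2 and 24 by voom with quality weights, and 55 without the 4 libraries. For 125 d minus 75 d, 0 were called (1957 unadjusted), 27 by DESeq2, 1 by voom and 1 without the 4 libraries, but 149, 189, 152 and 254 without mutant replicate 1, 2, 3 or 5 of 125 d, and 20 without WT replicate 2 of 75 d. For 225 d minus 125 d, 0 were called (1784 unadjusted), 23 by DESeq2, 0 by voom and 0 without the 4 libraries, and 12 without mutant replicate 5 of 125 d. For 225 d minus 30 d, 4 were called, 52 by DESeq2, 56 by voom and 162 without the 4 libraries. Bin1 (ENSMUSG00000024381; chromosome 18, 32377230 to 32435737), which shapes the T-tubules of heart muscle, rose more at 225 d, by 2.89 ± 0.50 (adjusted p = 0.0129), with 41.4 ± 13.6 against 4.81 ± 0.682 CPM at that age. Arhgef2, a protein bound to microtubules (ENSMUSG00000028059; chromosome 3, 88605966 to 88648052), rose more by 1.21 ± 0.23, with 68.2 ± 10.3 against 21.6 ± 1.58 CPM. Efnb3 fell more, with -2.50 ± 0.48. Without WT replicate 1 or 2 of 30 d no gene was called, Bin1 standing at 2.80 and 2.85, and 2 were without WT replicate 3, while 10 and 8 were without mutant replicate 1 or 2 of 30 d. Efnb3 was not called without WT replicate 3 (-2.63) or mutant replicate 1 (-2.08) of 30 d, or mutant replicate 4 of 225 d (-2.41). Arhgef2 was not called without WT replicate 3 (1.25) or mutant replicate 3 (1.11) of 30 d, or with no filter on low counts (1.22). With the replicate block neither was called (-2.43 and 1.19).

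Among the lists, the interaction of 75 d minus 30 d held with an estimated correlation for serine and one-carbon metabolism alone, whose mean effect was 0.60 larger at 75 d (adjusted p = 0.00285 with an estimated correlation), with 0 of 20 genes called and 4 higher adjusted over the list alone. With the preset correlation 19 lists were called in that comparison, 29 in 125 d minus 75 d, 30 in 225 d minus 125 d and 13 in 225 d minus 30 d, and none of the calls of the last 3 comparisons held with an estimated correlation. For 225 d minus 30 d the mean was 1.24 for the integrated stress response and -0.51 for branched-chain amino acid breakdown (adjusted p = 0.209 and 0.200 with an estimated correlation). The 29 calls of 125 d minus 75 d became 17 without mutant replicate 4 of 125 d and 5 without the 4 libraries, and the 30 calls of 225 d minus 125 d became 12 without the 4 libraries.

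WT hearts at 225 d were compared with WT hearts at 30 d as a background of age, from which the file sets of these ages cannot be separated. Col1a1, the main fibrillar collagen, fell by 1.97 ± 0.33, from 248 ± 63.6 to 63.4 ± 10.5 CPM. Pdk4 rose by 2.25 ± 0.44, from 20.9 ± 4.10 to 99.2 ± 22.7 CPM, and Bdh1, an enzyme of ketone body use, by 2.21 ± 0.41. Matrix and fibrosis genes fell in 4 of 23 with 19 not called (6 adjusted over the list alone; mean -0.61, adjusted p = 0.497 with an estimated correlation). Cytosolic ribosomal protein genes rose in 9 of 79 with 70 not called (30 adjusted over the list alone; mean 0.46, adjusted p = 0.415 with an estimated correlation). In all 269 genes were called, 79 higher and 190 lower (29.4% higher, and 10.3% of 474 with total counts as size factors), and 1049 without the 4 libraries. Without WT replicate 1 of 30 d 16 genes were called and without WT replicate 2 of that age 124, and Pdk4 (2.14) and Bdh1 (2.08) were not called without replicate 1, while Col1a1 was called whichever library was left out. The 2 ages also differ in the annotation version of their files. Of the named falls, CT010467.1 was not called with DESeq2 or with only these ages in the fit. Nor was mt-Rnr2 (-2.23), a ribosomal RNA of the mitochondrial genome, called without WT replicate 1 of 30 d (-1.10). Of 22 called lists, 19 higher and 3 lower, 0 held with an estimated correlation, and 12 were called without WT replicate 1 of 30 d.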

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

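Of the tests in this part, those of a mixed sample, of the macrophage markers and of the 30 d count without the 4 libraries were chosen after the results were seen, as were the names of Tmem150c and Fgf21. A library was listed when its gap to the nearest other library of its group was too large for the group's range (Dixon's test). Chance alone lists about 1 in 20 groups. Of 237 groups tested 30 were listed, where 11.8 would be by chance.

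Mutant replicate 4 of 125 d was listed for lymphocyte markers (score 5.43), endothelial markers (-2.28), fibroblast markers (-2.15), smooth muscle markers (-1.97) and macrophage markers (-0.43). If RNA of another organ diluted heart RNA in this library, contraction genes that were not called at 75 d or 225 d should be low in it together. The median ratio of 14 such genes to the other 125 d libraries was 0.157, which is consistent with a mixed sample. Whether the heart in it was mutant could not be told, since thymus reads push both measures. The median position was 0.0950 (0.00777 to 0.198) for 130 genes lower in mutants, where a WT heart would lie near 0, and 1.44 (1.24 to 1.71) for 181 genes higher in mutants, where a mutant heart would lie near 1.

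Macrophage markers were higher in mutant hearts at 75 d and 225 d. A lower share of cardiomyocyte RNA would raise the markers of every other cell type alike, but the difference of macrophage minus endothelial scores was 1.43 at 75 d (exact p = 0.00794) and 1.33 at 225 d (exact p = 0.00126), which argues against it. Blood left in the tissue would raise red blood cell genes too, but macrophage minus red blood cell scores differed by 1.54 (exact p = 0.0397) and 1.64 (exact p = 0.00126), which argues against it as well. Neither test was run at 30 d or 125 d. More macrophages per heart, or more of these transcripts per macrophage, may account for the rise, and no test here separated these.

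At 30 d 7 genes were called. With 3 against 3 libraries drawn 60 times from the later ages, the lowest count was 392, which argues against the number of libraries as the whole reason. With the 4 libraries left out, none of them of 30 d, 74 genes were called, so part of the low count may lie in the spread that these libraries add to a shared fit. A fit of the 30 d libraries alone, which is free of that spread but has only 6 libraries to estimate its own, called 9, so this stays open. A weaker effect of the mutation in young hearts stays open, and so does the lower depth of this age.

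Other splits of the same libraries into groups of the same sizes, 100 where there were that many, tested whether chance could be excluded for the counts of genes. At 75 d 1706 genes were called and at most 45 in another split (1 split of 100 as large, the real one included), at 125 d 4581 and at most 3120 (1 of 100), at 225 d 2559 and at most 607 (1 of 100), and in WT hearts between 30 d and 225 d 269 and at most 87 (1 of 100). The split with 3120 genes at 125 d relabelled only 2 libraries, so it kept much of the genotype effect. At 30 d there were only 10 splits, too few to exclude chance, and 4 were as large, with 7 genes in the real one and 1055 in the highest other. That split, of WT replicates 1 and 2 and mutant replicate 2 against the others, points to structure among the 30 d libraries other than genotype. For the interactions the splits were no test of chance, because labels redrawn within each age can leave the genotype effect of 1 age in the contrast. The real count was 0, 0, 0 and 4 for 75 d minus 30 d, 125 d minus 75 d, 225 d minus 125 d and 225 d minus 30 d, and the highest other 1034, 1903, 2930 and 3029. The split with 1034 kept all 5 mutant libraries of 75 d together and that with 3029 all 5 of 225 d.

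For the lists, the real count at 30 d was 15 and the highest other 11 (1 of 10 splits as large), too few splits to exclude chance. It was 24 and 25 at 75 d (6 of 100), 27 and 31 at 125 d (12 of 100), and 22 and 24 at 225 d (8 of 100). Chance was not excluded for the number of called lists at these ages, but these splits could not decide it. Those that keep most libraries of a genotype together hold part of its effect. At 225 d a split with 24 lists relabelled only 2 libraries, while at 125 d one with 29 lists relabelled 6, which mixes the genotypes. For WT age the counts were 22 and 19 (1 of 100), which argues against chance but cannot separate age from the file sets. For the interactions, where the splits were no test, the real and highest other counts were 19 and 21 for 75 d minus 30 d, 29 and 29 for 125 d minus 75 d, 30 and 28 for 225 d minus 125 d and 13 and 20 for 225 d minus 30 d.

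Among the differences between ages, the interaction tests listed Bin1 (2.89), Arhgef2 (1.21) and Efnb3 (-2.50) for 225 d minus 30 d, and Tmem150c (-4.22), a membrane protein outside the rule for naming genes. They listed the mean of serine and one-carbon metabolism for 75 d minus 30 d (0.60), and 19, 29, 30 and 13 called lists for the 4 interactions in the order above.

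Other libraries were listed as far from their groups with these values. WT replicate 5 of 75 d had 9.03 M counts and an adipocyte score of 4.44, and mutant replicate 5 of 225 d had 26.7% of its counts from the mitochondrial genome. Atrial scores were 2.61 in mutant replicate 4 of 75 d and 4.25 in mutant replicate 1 of 125 d, the fibroblast score was 0.35 in WT replicate 1 of 125 d, and the red blood cell score was 2.91 in WT replicate 4 of 125 d. In CPM, mutant replicate 5 of 225 d held Atf4 at 820, Atf5 at 623, Ddit3 at 207, Asns at 122 and Hmox1 at 27.9. Among WT libraries of 225 d, Asns was 4.66 in replicate 6, Pycr1 1.61 in replicate 7, Nppa 12805 and Nppb 39.5 in replicate 1 and Hmox1 5.5 in replicate 2. Among WT libraries of 125 d, Phgdh was 0.456 in replicate 5, Nppa 2446 in replicate 1, Nppb 19.9 in replicate 6, Acta1 1739 in replicate 2 and Pdk4 171 in replicate 4. Ppargc1a was 62.1 in WT replicate 1 of 75 d, Hmox1 13.8 in mutant replicate 3 of 75 d and Fgf21 1.66 in mutant replicate 5 of 125 d.

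Fgf21, a hormone of the mitochondrial stress response, had too few reads to be tested. It had at least 1 read in 18 of 18 mutant libraries, with 14 as the highest and 88 in all, and 0 in 21 of 21 WT libraries.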

How the results depend on the processing

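The fits without the 4 libraries and with total counts as size factors were chosen after seeing the data, and where a value moved, the cause was not tested unless stated. Of 9956 values of named genes and lists under the alternatives, 9026 kept their direction and their side of the threshold, 813 kept the direction and lost the call, 78 kept it and gained a call, and 39 turned. The 6 correlations between ages were repeated in 1 way only, with genes of an average log2 CPM of at least 4, where they ran from 0.44 to 0.83 in place of 0.35 to 0.78. Libraries of 30 d had the lowest mean depth (5.41 M in WT and 4.28 M in mutant hearts), and whether depth limited their calls was not tested.

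For called genes at 30, 75, 125 and 225 d (7, 1706, 4581 and 2559 in the report), DESeq2 gave 25 at 30 d, voom with quality weights 21, 4343 at 75 d and 4800 at 225 d, total counts 45, 2655, 8313 and 4297, a fit of the compared ages alone 3832 at 75 d, 1410 at 125 d and 3979 at 225 d, and the fit without the 4 libraries 74 at 30 d. Leaving out 1 library gave 3 to 9, 1303 to 1603, 3531 to 5141 and 1903 to 2431.

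For the interactions of 75 d minus 30 d, 125 d minus 75 d, 225 d minus 125 d and 225 d minus 30 d, DESeq2 gave 3, 27, 23 and 52. Voom gave 24 in the first, 1 in the second and 56 in the last. In the same comparisons 55, 1 and 162 were called without the 4 libraries, with total counts 47 in the second and 9 in the last, and with the compared ages alone 7 in the first and 56 in the last. Leaving out 1 library gave 0 to 0, 0 to 254, 0 to 12 and 0 to 10. WT age gave 482 with DESeq2, 4014 with voom, 1049 without the 4 libraries, 474 with total counts, 1069 with the compared ages alone, 179 with the atrial covariate, 129 with no filter on low counts, and 16 to 404 without 1 library.

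For called lists at 30, 75, 125 and 225 d, the 4 interactions and WT age, camera with an estimated correlation gave 3, 6, 3, 6, 1, 0, 0, 0 and 0. Fry gave 4, 14 and 14 at 30, 75 and 225 d, 1, 1, 0 and 1 in the interactions and 2 for WT age. Without the 4 libraries 5 were called in 125 d minus 75 d and 12 in 225 d minus 125 d. Leaving out 1 library gave 9 to 20, 17 to 31 and 12 to 22 in 75 d minus 30 d, 125 d minus 75 d and WT age.

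Replicate numbers did not pair the libraries: same-numbered libraries of the 2 genotypes correlated with a mean r of -0.03, -0.03, 0.13 and -0.05 at the 4 ages, and others with 0.02, 0.01, -0.02 and 0.01. With the number as a block, 2839 genes were called at 125 d, 1650 at 225 d and 2 in 225 d minus 30 d. With this block Gdf15, Pdk4 and Srxn1 at 30 d were not called (5.90, 2.68 and 2.58), and Acta1 at 30 d stood at -0.0851.

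Some genes turned in sign. With voom, turned values were those of Nppb (-0.31), Acta1 (-0.33) and Timp1 (-0.44) at 30 d, and Nrf1 (-0.13) at 125 d. With the Xist covariate it was that of Acta1 at 30 d (-0.13). With total counts they were those of Chchd3 (0.0862) and Opa1 (0.0313) at 125 d, and Pdss2 (0.0255) at 225 d. Without the 4 libraries they were those of Ucp1 at 75 d (3.37), Nrf1 at 125 d (-0.14) and Nppa at 225 d (-0.15). Nppa at 225 d also stood at -0.00394 with RLE size factors, -0.00395 with DESeq2 and -0.00439 with the compared ages alone.

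Without 1 library, values that turned ranged at 30 d from -0.58 to 0.39 for Acta1, -0.81 to 0.99 for Cth, -0.62 to 0.00214 for Myh6, -0.90 to 0.15 for Nppa, -0.47 to 0.92 for Nppb, -0.12 to 0.60 for Postn, -0.0716 to 0.81 for Timp1, and -0.34 to 0.0687 for the complex I list. At 75 d they ranged from -0.17 to 0.83 for Nppa and -8.30 to 3.41 for Ucp1. At 125 d they ranged from -0.0671 to 1.18 for Nrf1 and -0.10 to 3.61 for the cell cycle list, and at 225 d from -0.39 to 2.39 for Nppa.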

Other observations

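The tests of the 2 relations in this part were planned before the values were seen, except for the choice of the genes named in the next 2 paragraphs from the lists.

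Hlf, a transcription factor that follows the circadian clock, fell by 1.54 ± 0.31 at 75 d, from 32.8 ± 9.55 to 11.2 ± 2.52 CPM, and by 1.59 ± 0.30 at 225 d, from 32.7 ± 2.99 to 10.9 ± 2.98 CPM. Dbp, of the same family, fell at 225 d (adjusted p = 0.0069), from 65.4 ± 11.8 to 24.7 ± 5.10 CPM. Of 15 clock genes 2 fell and 13 were not called at 75 d (3 adjusted over the list alone), and 3 fell, 1 rose and 11 were not called at 225 d (6 and 1 adjusted over the list alone). The list calls at these ages were lost with an estimated correlation (adjusted p = 0.408 and 0.483), and the hour of dissection was not given in the sources used here.

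Transcripts of the muscle form of a ribosomal protein were lower in mutant hearts, and those of the general form were higher. Whether both changed in the same cells was not tested. Rpl3l, the form of striated muscle (ENSMUSG00000002500; GRCm38.p6, chromosome 17, 24727820 to 24736143), fell by 2.31 ± 0.29 at 75 d, from 213 ± 46.5 to 43.0 ± 8.49 CPM, and at 225 d it stood at 36.7 ± 13.8 against 207 ± 39.2 CPM. Rpl3 (ENSMUSG00000060036; chromosome 15, 80077791 to 80091868) rose by 1.10 ± 0.14 at 75 d, from 94.8 ± 12.1 to 203 ± 18.3 CPM, and by 1.16 ± 0.13 at 225 d. Mitochondrial chaperones and proteases were not called as a list at 75 d, with 1 of 18 higher and a mean of 0.32, or at 225 d, with 3 higher, 1 lower and a mean of 0.22. Glycolysis had 4 of 20 higher and 4 lower at 75 d, and autophagy 3 of 15 higher and 1 lower, and neither list was called.

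Among the 18 mutant libraries, centred by age, 2 relations were tested with the score of the integrated stress response. A stronger response was predicted where messenger RNAs of the mitochondrial genome were lower, but r was 0.90 (rho = 0.60, permutation p = 0.0376, adjusted p = 0.0376), the opposite sign. Without mutant replicates 4 and 5 of 125 d r was 0.45 (permutation p = 0.349), so a relation of either sign was not shown beyond these libraries. Mutant replicate 4 of 125 d held 14.8% of its counts from the mitochondrial genome, the lowest share of its group. With macrophage markers r was 0.86 (rho = 0.65, permutation p = 0.00395, adjusted p = 0.00790) as predicted. The 2 libraries farthest from the median were mutant replicate 4 of 125 d, which may be a mixed sample, and mutant replicate 4 of 75 d, which was not among the 4 libraries with RNA of another organ. Without them the sign was kept with r = 0.63 and rho = 0.55 (permutation p = 0.0609). In both relations the scores were centred by age before libraries were left out, and were not centred again. The remaining 125 d mutant libraries therefore kept an offset from mutant replicate 4, and neither r without the far libraries is free of it. Dilution of heart RNA in mutant replicate 4 of 125 d may lower these scores together, and what links them was not tested.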
